A study of Homo sapiens with 12 samples.

How the data were processed

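Total RNA from HEK293, a human embryonic kidney cell line, was measured on 12 Illumina bead arrays. Per the labels' protocols, RNA was extracted with Trizol, cleaned and treated with DNase on RNeasy columns, and biotin-labelled cRNA was made with the Ambion MessageAmp kit. Cells carried either a Mock construct or an RPF-1 cDNA in the pTRE2puro vector, which is switched on by taking tetracycline (Tet) out of the medium. They were cultured for 48 h with Tet (Tet+) or without it (Tet-).

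Signals were read with BeadStudio, per the submitters' processing notes; its version is not given in the sources used here. The deposited intensity values of each probe on each array come with a detection p-value, per the file headers, without any normalization. The deposited detection p-values moved in steps that match 708 negative control probes, and the controls themselves were not used here. The authors also deposited a processed table of intensity values on the linear scale. That table was checked against a quantile normalization of the unprocessed signals with no background subtracted: the median difference was 0.00624%, the largest was 2.07%, and the rank correlation on every array was 1.

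The main values were computed from the unprocessed signals. Background was corrected by the normal plus exponential model of limma, with the background inferred from the detection p-values and an offset of 16, then arrays were quantile normalized and taken to log2. Of 22184 probes, 19715 carried 1 gene symbol, 2469 carried none and 0 carried several. Probes with a detection p under 0.05 on at least 3 arrays were kept, which left 14752. For each gene symbol the kept probe with the highest mean over the 12 arrays was used, and probes without a symbol stayed as single features, so 13228 features were tested, 11824 of them with a symbol. Where a gene had several probes, those not used are left out of its value. Symbols are current ones from the RefSeq gene table, and 20 gene identifiers of the array annotation were not in it. No genome build is named for the probes, so no coordinates are given. The level of the transfected factor itself is not reported here.

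The model in limma 3.58.1 with R 4.3.3 had 1 coefficient for each of the 4 groups of 3 arrays, which left 8 residual degrees of freedom, with a prior of 3.31. Adjusted p-values are Benjamini-Hochberg values over all features, and a gene was called at an adjusted p under 0.05 with no fold minimum. The 5 contrasts were RPF1 Tet- against RPF1 Tet+, Mock Tet- against Mock Tet+, the difference between these Tet effects, RPF1 Tet+ against Mock Tet+, and RPF1 Tet- against Mock Tet-. Genes called with the same sign in the first contrast and in the difference of the Tet effects are named induction genes. These contrasts share arrays, so the induction genes are a filter and not an independent check. Every standard error of a log2 change is that of limma.

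Gene lists, 37 in number, were written from general knowledge of developmental regulators, signalling pathways, cell type markers, the cell cycle and stress responses. They were tested with camera at a preset correlation of 0.01 wherever at least 5 members were tested, with adjustment over the lists of a contrast. Named genes follow a rule. In RPF1 Tet- against RPF1 Tet+ these are the 12 named genes that rose most and the 12 that fell most among called genes whose 3 Tet- values lay all above or all below the 3 Tet+ values, plus up to 4 called members of each list with the largest change. In the difference of the Tet effects and for the induction genes they are the 10 largest each way. In the other contrasts they are the 6 largest each way and up to 4 called members of each list past the threshold, or, with no calls, the 3 smallest p each way given as values. The groups, contrasts, lists, named gene rule and alternatives were chosen before the data were examined, except 1 alternative that leaves out 4 arrays. These 4, said below to deviate together, are the array of each group with the highest score on 1 component of the deviations from group means. That each group has 1 follows from this rule. The phrase is a label only, as the Mock arrays of the set largely lacked the pattern of its RPF1 arrays in the genes given below. Tests of explanations that the closing section names as chosen after the result was seen, and the folds and list counts by chip, were added later. A few genes outside the rule are named where a small count asks for it, and these were chosen after their values were seen.

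Alternatives were the authors' values, no background correction, median scaling, an offset of 50, no detection filter, a detection p under 0.01 on all 12 arrays, all kept probes, only the 6 arrays compared, an intensity trend with a robust prior, array weights, and a minimum absolute log2 change of 1. Others were chip as a fixed or a random block, the one chip with all 4 groups, a replicate block, each array left out in turn, and for lists an estimated correlation and fry. The pipeline was tested on simulated data with 13228 features, of which 67 were changed by a log2 of 0.5, 67 by 1 and 66 by 2. In the RPF1 Tet- against RPF1 Tet+ contrast it called 43.3%, 94% and 100% of these, with 4 false calls among 162. For the difference of the Tet effects the shares were 4.48%, 80.6% and 100%, with 6 false calls among 129, so small differences of Tet effects are mostly missed. The simulated values were drawn independently for each gene, with the same fitted spread in all groups and no difference between chips. The few false calls thus do not show how many the real arrays hold. Figures were drawn with Python 3.11.15, matplotlib 3.10.9 and pandas 2.3.3.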

Results

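Expression was measured in 12 arrays of HEK293 cells in 4 groups of 3: Mock Tet+, Mock Tet-, RPF1 Tet+ and RPF1 Tet-. Between 13568 and 14493 probes were detected per array, and median raw signals lay between 277 and 357. The correlation between arrays of a group was 0.989 to 0.996, across genes, which are not independent replicates. The labels do not say whether the 3 replicates of a group are separate cultures, so p-values measure only the spread between these samples, and the number of arrays limits the precision. The arrays came from 3 chips: the first held Mock Tet+ 1 and 2, the third held RPF1 Tet- 2 and 3, and the second held the other 8. Within the second chip, RPF1 Tet- and Mock Tet+ have 1 array each, so values within it rest on few arrays and assume that a single array varies as the others do. Values with chip as a fixed block, or on that chip alone, are given beside counts and list results. "At least N-fold" is printed for a gene undetected on all 3 arrays of 1 group by any of its probes: it is the other group's mean against, on each array of the undetected group, the higher of the gene's own value and the lowest normalized signal among probes detected there.

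The main comparison, RPF1 Tet- against RPF1 Tet+, asks which genes change when RPF-1 is switched on. In RPF1 Tet- cells HES5, NPPB and CITED1 rose most among genes with a symbol, and CPA4, BMP5 and ANXA1 fell most. HES5, a repressor induced by Notch signalling (probe ILMN_1794742), rose 18.6-fold, a log2 change of 4.22 (SE 0.38, n = 3 per group, limma adjusted p = 3.45e-05). In RPF1 Tet+ 1 and 2 it was at 6.595 and 6.301, near the lowest signals of detected probes there (6.124 and 6.196). Its exact fold thus depends on values near background. NPPB, the precursor of brain natriuretic peptide (ILMN_1763382), rose by a log2 of 4.19 (SE 0.36, limma adjusted p = 2.51e-05), and CITED1, a transcriptional coregulator of the developing kidney, rose by 3.64 (SE 0.11, limma adjusted p = 1.39e-08). In RPF1 Tet+ 3 NPPB was at 6.017, below the lowest signal of detected probes there (6.044), so its fold rests in part on background. ANXA1, a membrane-binding annexin, fell (log2 change -3.29, SE 0.18, limma adjusted p = 5.03e-07), as did TFPI, an inhibitor of tissue factor (-2.87, SE 0.10, limma adjusted p = 2.33e-08). BMP5, a bone morphogenetic protein, was at least 8.90-fold lower (limma adjusted p = 3.25e-08), from 9.16 ± 0.03 (SD, n = 3) in RPF1 Tet+ to no detection on any RPF1 Tet- array.

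Group means show how far these genes lay from the Mock cells. HES5 had a log2 normalized signal of 6.74 ± 0.28 (SD, n = 3) in Mock Tet+, 6.82 ± 0.18 in Mock Tet-, 7.02 ± 1.01 in RPF1 Tet+ and 11.24 ± 0.31 in RPF1 Tet-. For CITED1 the means in that order were 8.64 ± 0.05, 8.63 ± 0.02, 8.15 ± 0.12 and 11.79 ± 0.23, and for ANXA1 they were 14.53 ± 0.05, 14.54 ± 0.14, 14.33 ± 0.01 and 11.04 ± 0.46. Other genes among the 12 that rose most were VGF, a secreted neuropeptide precursor, by a log2 of 2.98, NPTX2, a neuronal pentraxin, by 2.91, the endoderm factor FOXA2 by 2.77 and TKTL1, a transketolase-like gene, by 2.65, though TKTL1 was detected on 1 of 3 RPF1 Tet+ arrays and its fold depends on values near background. FOS, an immediate early gene, was at least 5.22-fold higher (limma adjusted p = 0.000519). Among the 12 that fell most were CPA4 (-3.44), the guidance cue SEMA3C (-2.73), NDUFV3, of respiratory complex I (-2.73), EDIL3 (-2.60), the cell cycle inhibitor CDKN2B (-2.52) and the receptor EPHA3 (-2.49). CPA4 was detected on 1 of 3 RPF1 Tet- arrays, so its fold too depends on such values. The folds of VGF, NDUFV3 and EDIL3 do so in part. VGF was at 5.985 in RPF1 Tet+ 1, where the lowest signal of detected probes was 6.124. NDUFV3 and EDIL3 were at 5.75 and 5.948 in RPF1 Tet- 3, where it was 5.983. None of the 24 genes of this rule, 12 in each direction, reversed with chip as a block or on the second chip alone. In both settings the contrast rests on RPF1 Tet- 1 as the 1 array of its group.

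**Figure D1:**
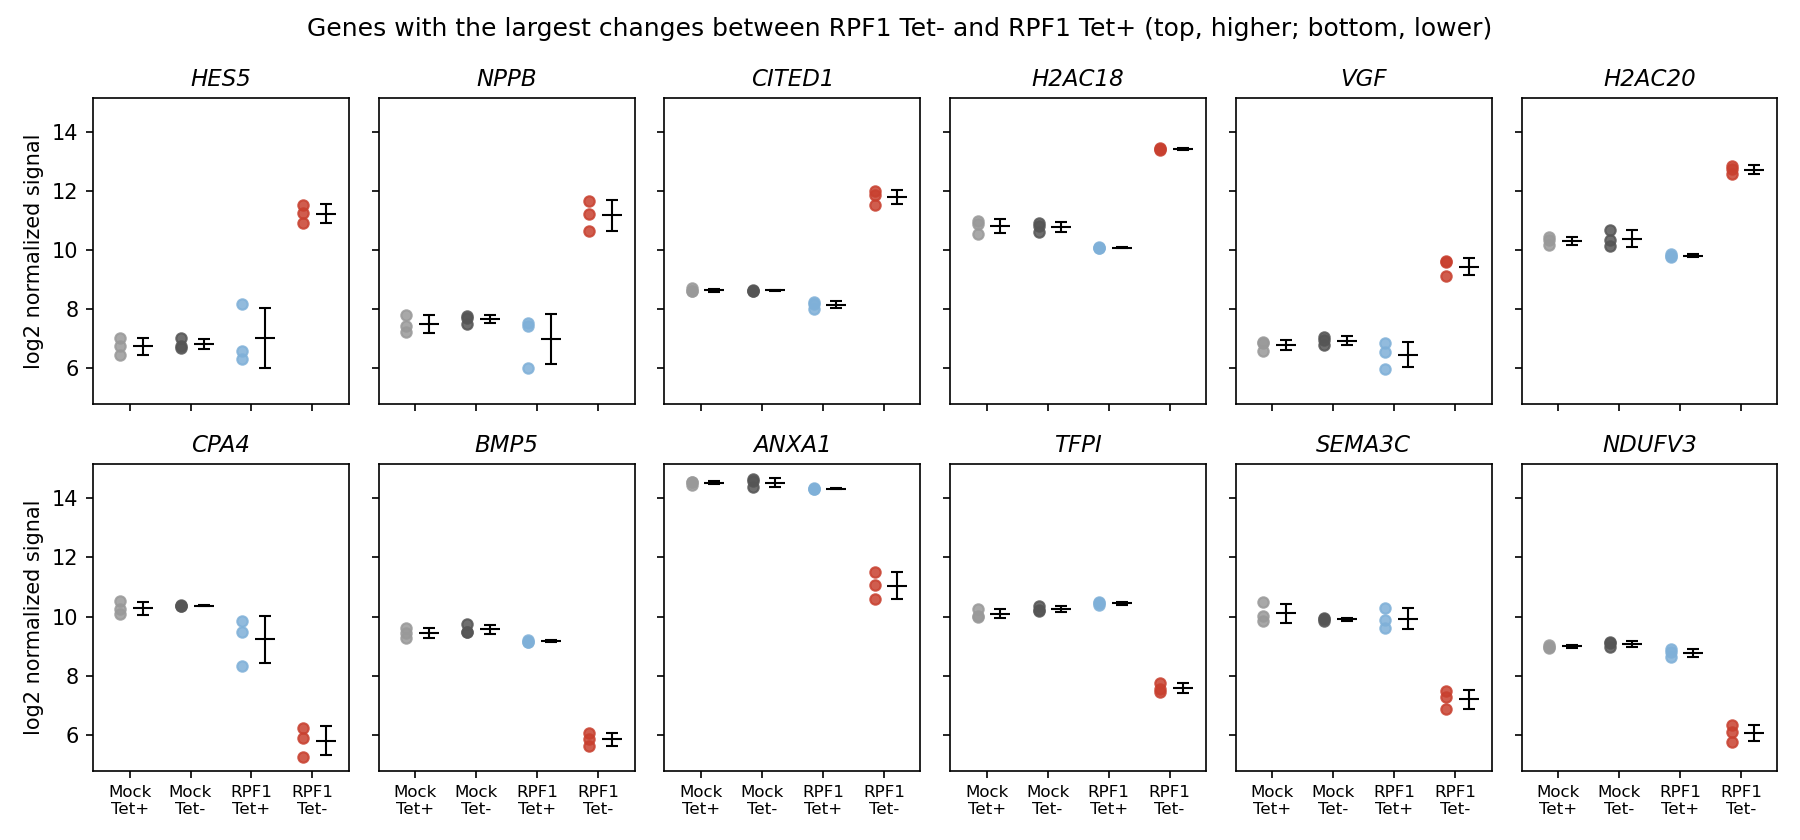
Log2 normalized signal (y axis) of 12 genes, 1 panel each, in the 4 groups; points are the 3 arrays of a group, and the bar beside them is the mean with its SD. The upper panels show 6 of the genes that rose most in RPF1 Tet- and the lower panels 6 that fell most; HES5, for example, was at 6.74 and 6.82 in the Mock groups, 7.02 in RPF1 Tet+ and 11.24 in RPF1 Tet-.

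Across the array, 1771 of 13228 features (13.4%) were called, 882 higher and 889 lower, and 252 of them, 152 higher and 100 lower, had an absolute log2 change of at least 1. With chip as a fixed block 421 were called (201 higher, 220 lower), 416 of which were among the 1771, and on the second chip alone 368 (180 higher, 188 lower), with 359 shared. The 1355 genes that lost their call with the block had a median absolute log2 change of 0.47 without it and, oriented by sign, 0.43 with it, while their median SE went from 0.11 to 0.15. With only the 6 RPF1 arrays in the fit 972 were called, and with array weights 3236. The count was 1139 without RPF1 Tet+ 1 and 1158 without RPF1 Tet- 3. Over all contrasts, 75 of 195 values of named genes lost their call with chip as a block and 83 on the second chip alone, and the genes named in this text for which either holds are marked.

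Of 41 homeobox and developmental factors outside the HOX and POU families, 16 rose, 3 fell and 22 did not pass the test; adjusted over the list alone, 18 rose and 3 fell. With the block, and on the second chip alone, 8 rose and 1 fell. FOXA2 rose by a log2 of 2.77 and IRX4 by 1.27, FOXF1 was at least 2.65-fold higher, and ALX1 fell (-1.30). The limma adjusted p of these genes lay between 4.6e-06 and 0.000274. The list's median log2 change was 0.21 (camera adjusted p = 0.00236; adjusted p = 0.0749 with an estimated correlation). It was 0.31 with chip as a block (adjusted p = 0.00399) and 0.31 on the second chip alone (adjusted p = 0.00239).

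Of 22 Notch pathway genes, 4 rose, 1 fell and 17 did not pass; adjusted over the list alone, 7 rose and 1 fell. With the block 3 rose and 0 fell by limma, and on the second chip alone 4 and 0. Besides HES5, the ligand DLL1 rose by a log2 of 1.65, and the glycosyltransferase LFNG by 0.88; the receptor NOTCH1, the remaining gene that rose, had a change of 0.68 (SE 0.12), a call lost with chip as a block (0.71, SE 0.18, adjusted p = 0.0776). The target HEY2 fell (-0.81, SE 0.16), a call lost with chip as a block (-0.61, SE 0.23, adjusted p = 0.222) and without 4 arrays that deviated together (adjusted p = 0.0573). The median change was 0.17, or 0.09 with 2 members below detection in 1 group set at their bounds (camera adjusted p = 0.0176; adjusted p = 0.1 with an estimated correlation). The list did not pass with chip as a block (median 0.07, adjusted p = 0.081) or on the second chip alone (median 0.07, adjusted p = 0.0689).

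Histone genes rose together more than any other list tested in this comparison. Of 17 tested, 13 rose, 1 fell and 3 did not pass, with the same counts of 13 and 1 when adjusted over the list alone. With the block, and on the second chip alone, 10 rose and 0 fell by limma. H2AC18 rose by a log2 of 3.34 (SE 0.12, limma adjusted p = 1.83e-08), H2AC20 by 2.91, H2AJ by 2.60 and H1-2, a linker histone, by 2.31. H2BC5 fell (-0.54, SE 0.16), a call lost with the block (-0.62, SE 0.24, adjusted p = 0.237) and on the second chip alone (adjusted p = 0.237). H3-3B (-0.04), H2AZ1 (-0.04) and H4C3 (0.02) did not pass. Most histone genes have near-identical copies, so which copy a probe reads is uncertain. The 13 that rose belong to 5 types, H1, H2A, H2B, H3 and H4. Within a type several probes may read the same transcript, so the 13 need not be separate rises. The median change was 1.46 (camera adjusted p = 6.38e-14; adjusted p = 0.1 with an estimated correlation), 1.47 with chip as a block (adjusted p = 7.91e-16) and 1.51 on the second chip alone (adjusted p = 2.33e-14).

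Of 44 genes of S phase and DNA replication, 4 rose and 0 fell by limma (3 and 0 adjusted over the list alone). Their median was 0.04 (camera adjusted p = 0.232). The 4 were SLBP, E2F2, ORC1 and GINS4, with log2 changes of 0.31 to 0.35, and with chip as a block none was called (0.40, 0.30, 0.23 and 0.33, SE 0.12 to 0.14, adjusted p 0.123 to 0.387). SLBP also lost its call without RPF1 Tet+ 2 or RPF1 Tet- 1 (adjusted p = 0.0505 and 0.0506), E2F2 without RPF1 Tet+ 1 or 2 (0.0506 and 0.0542), ORC1 without RPF1 Tet+ 1 or 3 or RPF1 Tet- 2 (0.057 to 0.0745) and GINS4 without any of 9 single arrays (0.053 to 0.122). Of 44 genes of G2 and mitosis, 0 were called by limma, with a median of 0.07 (camera adjusted p = 0.144).

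Of 29 p53 targets and growth arrest genes, 13 rose, 4 fell and 12 did not pass; adjusted over the list alone, 19 rose and 4 fell. With the block 4 rose and 2 fell, and on the second chip alone 2 and 2, so called members showed no excess of rises there. TP53I3 rose by a log2 of 1.57 (SE 0.19), though not past the threshold on the second chip alone (1.29, SE 0.26, adjusted p = 0.0517), and CDKN2D, an inhibitor of cyclin-dependent kinases, by 1.25. GADD45G rose by 1.13 (SE 0.21), a call lost with the block (0.73, SE 0.21, adjusted p = 0.111) and on the second chip alone (adjusted p = 0.133). MDM2, whose product degrades p53, rose by 0.96 (SE 0.18), a call lost on the second chip alone (1.05, SE 0.24, adjusted p = 0.0812), and CDKN1A, the p21 inhibitor, by 0.52 (SE 0.15), a call lost with the block (0.49, SE 0.20, adjusted p = 0.274) and there (adjusted p = 0.232). Both were chosen after their values were seen. The 4 that fell were ZMAT3 (-0.47) and the kinase inhibitors CDKN2B (-2.52), CDKN2A (-0.86) and CDKN1B (-0.66). Calls were lost for ZMAT3 with the block (-0.39, SE 0.12 against 0.08 without it, adjusted p = 0.139) and on the second chip alone (adjusted p = 0.154), and for CDKN1B (-0.68, SE 0.17 against 0.11, adjusted p = 0.0682, and 0.102). The median was 0.42 (camera adjusted p = 0.00236; adjusted p = 0.1 with an estimated correlation), 0.30 with chip as a block (adjusted p = 0.0181) and 0.30 on the second chip alone (adjusted p = 0.0206).

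Of 18 mesenchymal and fibroblast markers, 2 rose, 5 fell and 11 did not pass; adjusted over the list alone, 2 rose and 6 fell. With the block, and on the second chip alone, 0 rose by limma and 4 fell. COL3A1, a fibrillar collagen (-2.18), N-cadherin CDH2 (-0.67) and vimentin VIM (-0.62) fell. ACTA2 rose by 0.97 (SE 0.24), a call lost with chip as a block (0.60, SE 0.30, adjusted p = 0.37) and without RPF1 Tet+ 1 or 2 or RPF1 Tet- 2 or 3 (adjusted p 0.0579 to 0.0729). The median was -0.28 (camera adjusted p = 0.0214; adjusted p = 0.1 with an estimated correlation), -0.17 with chip as a block (adjusted p = 0.0355) and -0.17 on the second chip alone (adjusted p = 0.0407).

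Of 8 blood cell markers, kept as a check for other cell types, 3 rose, 0 fell by limma and 5 did not pass, and 5 rose and 0 fell adjusted over the list alone. With the block, and on the second chip alone, 2 rose and 0 fell by limma. HBA1, an alpha globin, rose by 1.89 and CD68, a lysosomal protein, by 0.60; LCP1, at 0.55 (SE 0.15), lost its call with chip as a block (0.69, SE 0.23, adjusted p = 0.161), with the authors' values (0.23, adjusted p = 0.0575) and without any 1 of 5 RPF1 arrays or Mock Tet- 3 (adjusted p 0.051 to 0.114). This list's median was 0.44 (camera adjusted p = 0.0214; adjusted p = 0.1 with an estimated correlation), 0.32 with chip as a block (adjusted p = 0.0319) and 0.32 on the second chip alone (adjusted p = 0.0407), and it did not pass without 4 arrays that deviated together (adjusted p = 0.054). PTPRC, carried by nearly all white blood cells, had a log2 change of -0.20 (limma adjusted p = 0.546). The lists of endothelial markers and of keratinocyte and carcinoma line markers, also of other cell types, held called genes but did not pass in this comparison.

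**Figure D2:**
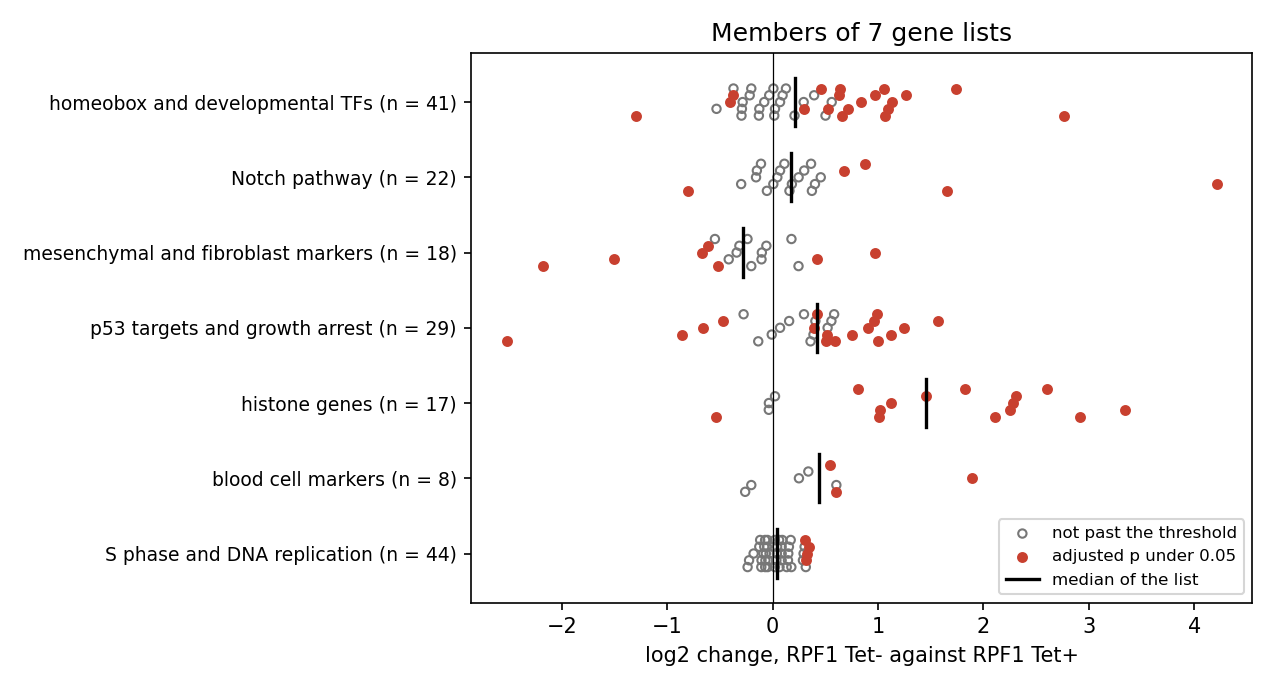
Log2 change between RPF1 Tet- and RPF1 Tet+ of each tested member (points) of the 6 lists past the camera threshold and of the S phase list; the black bar is the list's median. The histone genes have a median of 1.46 and the S phase genes one of 0.04.

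Other lists held called genes without passing as a whole (camera adjusted p from 0.0814 for apoptosis regulators to 0.995 for oxidative stress and NRF2 genes, the latter with a median of 0.02 and a mean of -0.02). Axon guidance genes moved both ways, with 8 of 33 higher and 9 lower (10 and 9 adjusted over the list alone, 3 and 6 with the block and 2 and 5 on the second chip). SEMA3A (-2.22, detected on 1 of 3 RPF1 Tet- arrays, near background) and its receptor NRP1 (-1.62) fell. Among 39 extracellular matrix genes 5 rose and 5 fell (6 and 6 adjusted over the list alone, 0 and 4 by limma with the block and 0 and 5 on the second chip). LAMA4 (-1.62) and COL5A2 (-1.40) were among those that fell. Of 18 cadherins and protocadherins 1 rose and 3 fell (1 and 3 adjusted over the list alone, 1 and 3 with the block and 1 and 3 on the second chip). PCDH7 (-2.40) and FAT4 (-1.15) fell, and CDH3 (1.13) rose. Of 21 neuronal genes 4 rose and 5 fell (4 and 5 adjusted over the list alone, 2 and 1 with the block and 1 and 1 on the second chip). Among them were MAP2, a dendritic microtubule protein (-1.79), and TUBB3, a neuronal tubulin (1.08).

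Kidney development regulators, of which 23 were tested, had 5 higher and 2 lower (6 and 2 adjusted over the list alone, 2 and 2 with the block and 2 and 1 on the second chip). Next to CITED1, LHX1 (0.75) rose, and EYA1 (-1.91) and BMP4 (-0.77) fell, BMP4 without passing on the second chip alone (-0.82, SE 0.17 against 0.10 on all arrays, adjusted p = 0.0568). Of 17 retina and eye genes 1 rose and 3 fell (1 and 4 adjusted over the list alone, 0 and 1 by limma with the block and 0 and 1 on the second chip). DACH1 (-1.74) was among those that fell. Of 5 POU domain genes 2 rose and 0 fell by limma (2 and 0 adjusted over the list alone, 1 and 0 by limma with the block and 1 and 0 on the second chip). POU2F2 rose by 0.75 and POU3F2 by 1.12 (SE 0.25), the latter not called with chip as a block (0.77, SE 0.34, adjusted p = 0.313) or with only the 6 RPF1 arrays in the fit (1.12, adjusted p = 0.0617). POU3F2 was detected on 1 of 3 RPF1 Tet+ arrays, near background. Of 25 HOX genes 4 rose and 2 fell (6 and 4 adjusted over the list alone, 1 and 0 by limma with the block and 1 and 0 on the second chip). HOXC13 was higher by 1.17.

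Among signalling genes, 7 of 32 in the TGF-beta and BMP pathway rose and 4 fell (7 and 6 adjusted over the list alone, 2 and 4 with the block and 2 and 3 on the second chip). The BMP antagonist GREM1 (-2.10) fell and INHBB (1.05) rose. In FGF and ERK signalling 5 of 30 rose and 3 fell (5 and 3 adjusted over the list alone, 4 and 0 by limma with the block and 4 and 0 on the second chip). DUSP5, a phosphatase of ERK, rose by 2.19 and FOSB, detected on 1 of 3 RPF1 Tet+ arrays and near background there, by 1.01. In the Wnt pathway 7 of 34 rose and 4 fell (9 and 5 adjusted over the list alone, 2 and 2 with the block and 1 and 1 on the second chip). FZD8 was higher by 1.13 (SE 0.15), a call lost on the second chip alone (1.02, SE 0.21, adjusted p = 0.0538). In the IGF axis 3 of 16 rose and 2 fell (6 and 2 adjusted over the list alone, 0 and 1 by limma with the block and 1 and 1 on the second chip). IGFBP7 (-1.15) fell, and IGF2 (1.31, SE 0.18) rose, a call lost with chip as a block (1.19, SE 0.28, adjusted p = 0.0551). IGF2 was detected on 1 of 3 RPF1 Tet+ arrays, so its fold depends on values near background.

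Of the stress and survival lists, apoptosis regulators had 4 of 26 higher and 0 lower by limma (5 and 0 adjusted over the list alone, 1 and 0 by limma with the block and 1 and 0 on the second chip). BIK rose by 1.27. Heat shock genes had 5 of 21 higher and 1 lower (5 and 1 adjusted over the list alone, 1 and 1 with the block and 1 and 1 on the second chip). HSPA6 was at least 1.82-fold higher and DNAJB4 (-1.03) fell. NF-kB and inflammatory genes had 3 of 15 higher and 0 lower by limma (4 and 0 adjusted over the list alone, 1 and 0 by limma with the block and 1 and 0 on the second chip). CCL2 rose by 1.15 (SE 0.21), a call lost on the second chip alone (1.42, SE 0.29, adjusted p = 0.054), as were those of the other 2, and the 1 called there is another gene. Interferon-stimulated genes had 5 of 27 higher and 1 lower (5 and 2 adjusted over the list alone, 0 and 0 by limma with the block and 0 and 0 on the second chip). Integrated stress response genes had 1 of 27 higher and 5 lower (2 and 5 adjusted over the list alone, 0 and 0 by limma with the block and 0 and 0 on the second chip). None of the 26 genes of MYC and ribosome biogenesis was called by limma, and of 59 cytosolic ribosomal proteins 0 rose and 3 fell (0 and 0 adjusted over the list alone, 0 and 0 by limma with the block and 0 and 0 on the second chip; median -0.02).

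Mock Tet- against Mock Tet+ asks what Tet itself does in cells without the RPF-1 construct. No gene was called: limma gave 0 of 13228 features, with 327 at an unadjusted p under 0.05 where chance gives 661, and a smallest adjusted p of 1. The genes with the smallest p are given as values only: ERBB2 had a log2 change of 0.53, HTR4 of 0.45, ZNF169 of 0.44, NPC1L1 of -0.51, MYRF of -0.53 and ZNF417 of -0.76. Of the 1771 genes called in RPF1 cells, the median absolute log2 change was 0.54 in RPF1 cells and 0.06 in Mock cells, and 47.8% had the same sign in Mock cells. The largest absolute change in Mock cells of any gene with a symbol was 0.79. Camera passed 0 of 36 lists (smallest adjusted p = 0.206, endothelial markers) and fry passed 0; with chip as a block camera passed 3, and 1 without Mock Tet- 2, and chip as a block called 0 genes. On simulated arrays, with changes placed in Mock Tet- and no difference between chips, 47.8% of log2 changes of 0.5 were called in this comparison. Tet effects of that size or below would thus often be missed. Both the fit and the simulation use a spread pooled over the 4 groups. The lowest correlation between arrays of a group was 0.994 in Mock Tet+ and 0.995 in Mock Tet-, against 0.992 in RPF1 Tet+ and 0.989 in RPF1 Tet-. The pooled spread may thus be too wide for Mock cells and too narrow for RPF1 cells. With only the 6 arrays compared in the fit, fewer features were called in RPF1 cells, and no gene named for Mock cells gained a call. Those fits also estimate the spread from fewer arrays, so they do not decide this.

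**Figure D3:**
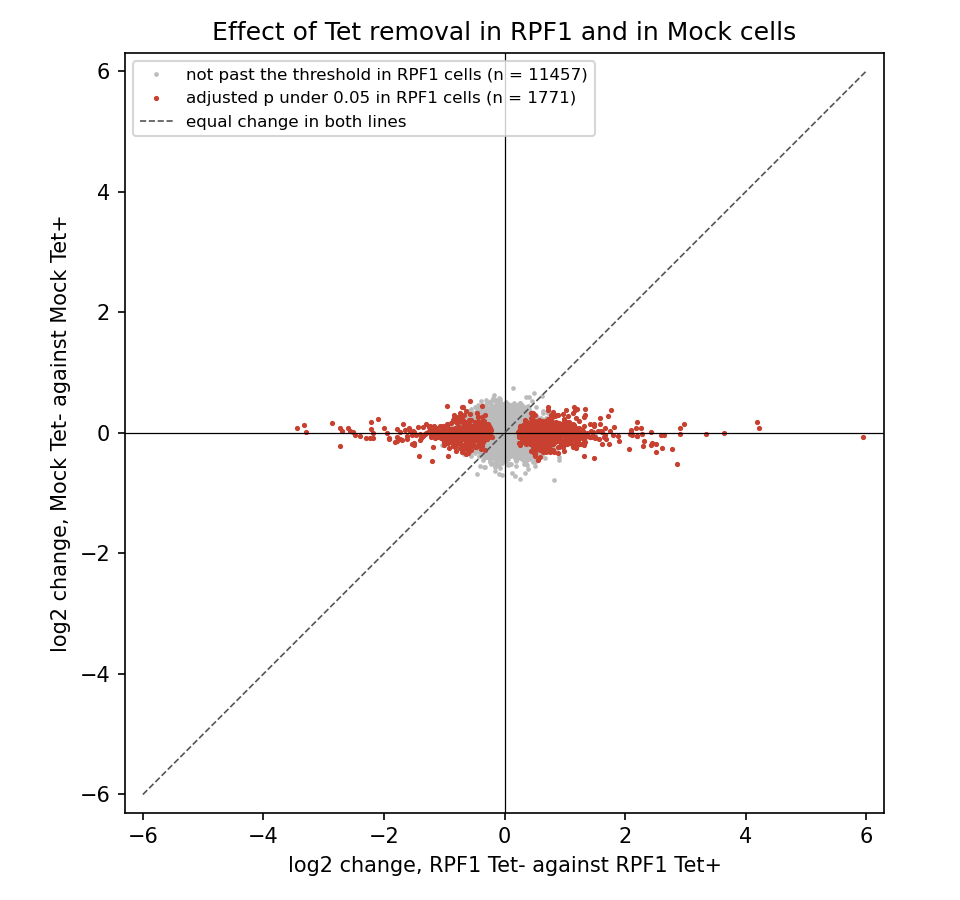
Log2 change on Tet removal in RPF1 cells (x axis) and in Mock cells (y axis), each point a tested feature; red marks the 1771 features called in RPF1 cells, and the dashed line marks equal change. Red points spread along the RPF1 axis, while on the Mock axis no gene with a symbol passes an absolute change of 0.79.

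The difference of the Tet effects asks which changes in RPF1 cells exceed those in Mock cells. The genes at its ends were largely those named above: the log2 change of CITED1 was 3.65 higher in RPF1 cells than in Mock cells, that of H2AC18 was 3.37 higher and that of FOXA2 was 3.04 higher. The difference was -3.30 for ANXA1 and -3.03 for TFPI, and the smallest limma adjusted p of this comparison was 6.09e-07. In all 679 features were called, 344 higher and 335 lower, 231 of them with an absolute log2 difference of at least 1. Induction genes, called with the same sign here and in RPF1 Tet- against RPF1 Tet+, numbered 662, 334 higher and 328 lower, 211 of them with an absolute log2 change of at least 1. This is 37.4% of the 1771, and the median SE of a difference, 0.17, was larger than the 0.12 of a single contrast. With chip as a block 98 features were called (96 shared) and 97 induction genes (95 shared), and on the second chip alone 77 of each (74 shared). Calls of 5 genes at the ends were lost while their differences stayed large and their SE grew. HES5, at 4.14 (SE 0.54), was not called with chip as a block (3.83, SE 0.82, adjusted p = 0.0832) or on the second chip alone (3.82, SE 0.88, adjusted p = 0.145). Nor was CPA4, at -3.53 (SE 0.47), with -3.12 (SE 0.68, adjusted p = 0.0881) and -3.10 (SE 0.69, adjusted p = 0.137). FOS, at least 2.63 higher with RPF1 Tet+ undetected, lost its call with the block (adjusted p = 0.152), where its fitted value went from 2.86 (SE 0.49) to 2.88 (SE 0.75). NPPB, at 4.01 (SE 0.52; 4.39, SE 0.73, adjusted p = 0.0615), and H2AC11, at 3.37 (SE 0.36; 3.21, SE 0.57, adjusted p = 0.0755), lost theirs on the second chip alone.

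Single arrays and weights moved these counts by more than 1.5 times. The difference called 418 features without RPF1 Tet- 3, 420 without RPF1 Tet+ 1 and 423 without Mock Tet- 3, and the induction genes numbered 410, 412 and 416. With array weights the counts were 1488 and 1413.

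The lists that differed between RPF1 and Mock cells were the histone genes, the developmental factors, the p53 and growth arrest genes, the Notch genes and the mesenchymal markers. Of the histone genes 12 of 17 had a higher and 0 a lower change by limma (13 and 0 adjusted over the list alone, 9 and 0 with the block and 8 and 0 on the second chip). Their median difference was 1.44 (camera adjusted p = 1.07e-15; adjusted p = 0.112 with an estimated correlation), 1.56 with chip as a block (adjusted p = 1.26e-17) and 1.59 on the second chip alone (adjusted p = 4.66e-16). The developmental factors had 11 higher and 2 lower, or 13 and 3 adjusted over the list alone, 3 and 1 with the block and 4 and 0 on the second chip, with a median of 0.24 (camera adjusted p = 0.00933; adjusted p = 0.112 with an estimated correlation). Without the 4 arrays that deviated together the median was 0.03 (adjusted p = 0.0163), so the size of this shift depends on those arrays. They did not pass with chip as a block (median 0.16, adjusted p = 0.0526) but did on the second chip alone (median 0.16, adjusted p = 0.0337). The p53 genes lay higher by camera, with a median difference of 0.43, though limma called 2 higher and 4 lower, or 11 and 4 adjusted over the list alone, 1 and 1 with the block and 0 and 1 on the second chip (camera adjusted p = 0.00971; adjusted p = 0.133 with an estimated correlation). The Notch genes had 4 and 0 by limma (4 and 0 adjusted over the list alone, 1 and 0 with the block and 0 and 0 on the second chip; median 0.16, camera adjusted p = 0.0242; adjusted p = 0.112 with an estimated correlation), and the mesenchymal markers 0 and 4, or 1 and 7 adjusted over the list alone, 0 and 2 with the block and 0 and 1 on the second chip (median -0.30, camera adjusted p = 0.0225; adjusted p = 0.112 with an estimated correlation). None of these last lists passed with chip as a block (p53 median 0.22, adjusted p = 0.219; Notch 0.11, 0.214; mesenchymal -0.24, 0.0646) or on the second chip alone (0.22, 0.212; 0.11, 0.156; -0.24, 0.0618).

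RPF1 Tet+ against Mock Tet+ compares the lines with Tet in the medium, the uninduced state per the labels. RPF1 Tet+ cells differed from Mock cells in many genes: GALC, a lysosomal galactosidase, was at least 6.20-fold lower (limma adjusted p = 4.76e-09), GSPT2 at least 4.26-fold lower and MAGEB2 at least 5.18-fold lower, and SOX11, a developmental factor, was lower (log2 change -2.55, SE 0.17, limma adjusted p = 1.17e-05). SOX11 was detected on 1 of 3 RPF1 Tet+ arrays, so its fold depends on values near background. Among genes that were higher, ZNF311 was at least 3.14-fold higher, RIPOR2 was higher by 1.84 (SE 0.20, limma adjusted p = 0.000404) and TAGLN, an actin-binding protein of smooth muscle, by 1.77 (SE 0.20, limma adjusted p = 0.000468). Counts were 2000 called features, 1009 higher and 991 lower, with 118 at an absolute log2 change of at least 1. With chip as a block 296 were called (150 higher, 146 lower, 287 shared), on the second chip alone 139 (136 shared), without Mock Tet+ 1 1096, without Mock Tet+ 3 1149 and without RPF1 Tet+ 1 1327. C1QTNF6, higher by 1.70 (SE 0.27) and detected on 1 of 3 Mock Tet+ arrays, near background, lost its call with the block (1.75, SE 0.40, adjusted p = 0.0571) and on the second chip alone (1.71, SE 0.41, adjusted p = 0.0905).

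In this comparison 3 lists passed. Of 27 interferon-stimulated genes 9 were lower and 0 higher by limma (14 and 1 adjusted over the list alone, 3 and 0 with the block and 2 and 0 on the second chip). IFITM3 (-1.18) and IFITM2 (-0.80), membrane proteins that restrict viruses, were among them. The list median was -0.34 (camera adjusted p = 0.000132; adjusted p = 0.112 with an estimated correlation), -0.34 with chip as a block (adjusted p = 0.000258) and -0.34 on the second chip alone (adjusted p = 0.00028). Of 17 histone genes 9 were lower and 0 higher by limma (10 and 1 adjusted over the list alone, 4 and 0 with the block and 2 and 0 on the second chip), among them H1-2 (-0.84) and H4C14 (-0.82), neither called on the second chip alone (-0.999, SE 0.18, adjusted p = 0.0576, and -0.97, SE 0.17, adjusted p = 0.0539). The list had a median of -0.55, or -0.50 with 1 member at its bound (camera adjusted p = 0.000109; adjusted p = 0.534 with an estimated correlation), -0.69 with chip as a block (adjusted p = 2.41e-06) and -0.69 on the second chip alone (adjusted p = 4.35e-06). Of 27 integrated stress response and amino acid genes 10 were higher and 0 lower by limma (13 and 1 adjusted over the list alone). The median was 0.26 (camera adjusted p = 0.00819; adjusted p = 0.465 with an estimated correlation), 0.22 with chip as a block (adjusted p = 0.036) and 0.22 on the second chip alone (adjusted p = 0.0385). PCK2 (1.03) and ASNS (0.59), the asparagine synthetase, were among them, and with chip as a block neither was called (1.06, SE 0.29, adjusted p = 0.0894, and 0.62, SE 0.14, adjusted p = 0.0558), nor was any of the 27 by limma.

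RPF1 Tet- against Mock Tet- compares the induced cells with Mock cells in the same medium, and joins the effect of induction with the difference between the lines. The genes at its ends were HES5 (log2 change 4.42, SE 0.38, limma adjusted p = 1.78e-05), FOXA2 (3.52, limma adjusted p = 6.43e-07), NPPB (3.52, limma adjusted p = 6.1e-05) and CITED1 (3.16, limma adjusted p = 1.35e-08) on the higher side. On the lower side were CPA4 (-4.58) and ANXA1 (-3.50), BMP5 was at least 11.8-fold lower and OLR1, a scavenger receptor, at least 11.5-fold lower. In all 4135 features (31.3%) were called, 2089 higher and 2046 lower, 399 with an absolute log2 change of at least 1. The count was 1256 with chip as a block (1228 shared) and 1136 on the second chip alone (1102 shared). Histone genes were the 1 list of 36 that passed, with 11 of 17 higher and 1 lower (11 and 1 adjusted over the list alone, 10 and 1 with the block and on the second chip). Its median was 1.27 (camera adjusted p = 1.18e-05; adjusted p = 0.59 with an estimated correlation), 1.28 with chip as a block (adjusted p = 5.17e-07) and 1.32 on the second chip alone (adjusted p = 1.12e-06). H2AC18 was higher by 2.64 and H2AC20 by 2.34 against Mock Tet-. Some rises in RPF1 Tet- ended at the Mock level, from a lower level in RPF1 Tet+. IRX4 differed by -1.25 between RPF1 Tet+ and Mock Tet+ and by -0.03 between RPF1 Tet- and Mock Tet-, CDH3 by -1.35 and 0.02, and TUBB3 by -0.94 and 0.08. Of the 1771 genes called on induction, 290 were called the other way in RPF1 Tet+ against Mock Tet+, and 207 of these were not called in RPF1 Tet- against Mock Tet-. A missing call does not show that a gene ended at the Mock level. DUSP5, among the 207, went from -1.425 to 0.822 (limma adjusted p = 0.0649), above the Mock level. The contrasts share the RPF1 Tet+ arrays, so errors of these arrays add to the 290.

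No list passed in any of the contrasts with an estimated correlation. Fry, which asks whether the members of a list move on balance one way without comparing them with other genes, passed 16 lists in RPF1 Tet- against RPF1 Tet+, 11 for the difference of the Tet effects, 8 in RPF1 Tet+ against Mock Tet+ and 15 in RPF1 Tet- against Mock Tet-. With chip as a fixed block camera passed 10, 5 and 2 lists in RPF1 Tet- against RPF1 Tet+, RPF1 Tet+ against Mock Tet+ and RPF1 Tet- against Mock Tet-. Without RPF1 Tet+ 2 it passed 9 for the difference of the Tet effects and 5 in RPF1 Tet+ against Mock Tet+, and without RPF1 Tet- 2 it passed 8 for the difference.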

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

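The tests of Tet removal, of S phase and of histone copies below, and the folds before and after the chip block, were chosen only after the result was seen; the tests across chips and of other splits of the samples were planned.

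These results stand out because the Tet effect differed between RPF1 and Mock cells by a test of the difference itself: 344 genes had a higher change in RPF1 cells and 335 a lower one. The log2 differences of the 10 largest higher genes were 4.14 for HES5, 4.01 for NPPB, 3.65 for CITED1, 3.37 for H2AC18, 3.37 for H2AC11, 3.04 for FOXA2, 2.93 for NPTX2, 2.84 for H2AC20, 2.83 for VGF and at least 2.63 for FOS. Those of the 10 largest lower genes were -3.53 for CPA4, -3.30 for ANXA1, a bound of -3.28 for BMP5, -3.03 for TFPI, -2.80 for NDUFV3, -2.68 for EDIL3, -2.61 for DNAJC12, -2.53 for CDKN2B, -2.52 for SEMA3C and -2.46 for EPHA3. FOS was undetected in RPF1 Tet+ and BMP5 in RPF1 Tet-, so their differences are bounds, and their place among the 10 follows fitted values. Camera adjusted p-values of the lists that differed were 1.07e-15 for histone genes, 0.00933 for developmental factors, 0.00971 for p53 and growth arrest genes, 0.0242 for Notch genes and 0.0225 for mesenchymal markers, none past the threshold with an estimated correlation.

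Of 100 splits that shuffled Tet labels within each line, 5, the real one included, gave as many calls for the difference as the real 679, with 842 the highest of the others, so this count does not exclude chance. The same held for the induction genes, where 5 of 100 splits reached 662 and the highest of the others was 802. The 11 splits drawn that kept the RPF1 groups together called at least 587, and no split that mixed those groups called more than 3. Splits that reached 679 thus moved Mock arrays alone, which showed no called Tet effect, so the share follows from the design and says nothing on whether chance grouped the RPF1 arrays. For RPF1 Tet- against RPF1 Tet+ the 10 splits are too few for a share under 0.05, with 1771 real calls and 0 as the highest of the others. For its lists, 4 of 10 splits, the real one included, reached the real 6, with 8 as the highest of the others. Splits that mixed the groups, with 0 called genes, thus passed as many lists. The number of lists past the threshold does not set the real grouping apart. That highest split puts RPF1 Tet+ 3 and RPF1 Tet- 2 on one side, the RPF1 arrays that deviate together. Without these and the Mock arrays with the highest score of their group, 7 lists passed.

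The first pattern weighed is the set of genes called between RPF1 Tet- and RPF1 Tet+. An effect of Tet itself is argued against: the median change of these genes in Mock cells, oriented by their change in RPF1 cells, was -0.00844 of the median change in RPF1 cells. A difference between chips stays open as a part of these changes, because 2 of 3 RPF1 Tet- arrays are on a chip of their own. With chip as a random block, the estimated correlation between arrays of a chip was low, at 0.0319. This estimate rests on RPF1 Tet- and Mock Tet+, the groups split between chips, so it does not decide the question. A test picked 1603 genes on RPF1 Tet- 2 and 3 against RPF1 Tet+ 1 and 2. The median change between the held-out arrays, both from the second chip, was 0.498 of that in the picking arrays. This lies between the bounds set for and against chips. Of the picked genes 79.5% kept their sign, against 51.8% of other genes. The held-out arrays also lay far apart on the component of within-group deviations described under other observations, at -14.4 (RPF1 Tet- 1) and 17.8 (RPF1 Tet+ 3). The ratio thus cannot separate chips from that component. Of the 1771, 1355 lost their call with chip as a block, but their median change went only from 0.47 to 0.43 while the median SE went from 0.11 to 0.15, so a lost call is not evidence for chips, and as the same arrays enter both fits the values do not exclude them.

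The second pattern weighed is the rise of histone genes in RPF1 Tet-. More cells in S phase is argued against, since the median change of S phase genes was 0.0264 of the histone median and their highest change was 0.35 against a histone median of 1.46. This assumes that S phase genes would rise about as much as histone genes. That assumption was not tested, so a smaller shift toward S phase stays open. A single copy read by the probes of all types is argued against by called members in 5 histone types, which share no sequence. Within a type, a copy read by several probes stays open, so the 13 called members need not be separate transcripts. Chips are argued against by a median on the second chip 1.03 times that on all arrays, and Tet itself by a median in Mock cells of -0.0179 of that in RPF1 cells. Labelled cRNA is primed from poly(A) tails, which most histone transcripts of dividing cells lack, so more polyadenylated histone RNA could raise these probes without more histone RNA in all. That was not tested here, and a direct or indirect response to RPF-1 also stays open.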

How the results depend on the processing

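One alternative, without 4 arrays that deviate together (Mock Tet+ 2, Mock Tet- 1, RPF1 Tet+ 3 and RPF1 Tet- 2), and its tests were chosen after seeing the data. No named gene that was called reversed under any alternative. The genes named in Mock Tet- against Mock Tet+ had no call, and they count as kept below where they stayed uncalled, whatever their sign. Of 195 values of named genes, 195 kept their call with an offset of 50, all kept probes or array weights, 193 with the authors' values or no background correction, 192 with a random chip block, 191 with an intensity trend and robust prior, 189 with median scaling, 186 with no detection filter, 178 with the replicate block and 171 without the 4 arrays. Chip as a fixed block kept 120, the second chip alone 112, and the 6 arrays compared 140 of 175; single arrays left out kept 2147 of 2340. A detection p under 0.01 on all 12 arrays left 122 to test, all kept, and removes genes that are off in 1 group.

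In the order RPF1 Tet- against RPF1 Tet+, difference of the Tet effects, RPF1 Tet+ against Mock Tet+, RPF1 Tet- against Mock Tet-, and induction genes, the main counts were 1771, 679, 2000, 4135 and 662. Chip as a fixed block gave 421, 98, 296, 1256 and 97, and on the second chip alone 368, 77, 139, 1136 and 77; both rest on the second chip, the one with more than 1 group. With an absolute log2 change of at least 1 they were 252, 231, 118, 399 and 211, a stricter threshold. Array weights gave 3236, 1488 and 1413 for the first, the second and the induction genes, and the 6 arrays alone gave 972 for the first; the cause was not tested. Leaving out single arrays gave 1139 to 1701, 418 to 668, 1096 to 2395, 2990 to 4261 and 410 to 651. Without the 4 arrays counts were 1529, 502, 1820, 3816 and 484, of which 1194, 377, 1401, 3204 and 373 were shared. Mock Tet- against Mock Tet+ gave 0 by limma (327 at an unadjusted p under 0.05) with the blocks and without single arrays.

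Lists past the threshold numbered 6, 5, 3 and 1 in the first 4 comparisons and 0 in Mock Tet- against Mock Tet+. The fixed chip block gave 10, 4, 5, 2 and 3, and with an estimated correlation 0 in each. With fry they numbered 16, 11, 8, 15 and 0, since fry does not compare a list with other genes. Without single arrays they ranged 6 to 9, 5 to 9, 3 to 5, 1 to 1 and 0 to 1. Without the 4 arrays they numbered 7, 5, 3 and 1. The cause was not tested except as said.

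With the replicate number as a replicate block, counts were 1380, 426, 1456, 3594 and 421 in the same order. The numbers do not pair the samples: arrays with the same number had correlations of deviations from the group means of -0.246 to 0.25, -0.401 to 0.415 and -0.324 to 0.149 for numbers 1, 2 and 3, so lost calls are not weaker effects. Signal over background limits genes near detection: LCP1 changed by 0.55 with background correction and 0.23 without it, and folds are bounds where a group is undetected.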

Other observations

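The tests of partial induction and of the difference between lines, and the component of shared deviations, were chosen only after the result was seen.

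The main component of the deviations from group means held 39.9% of the variance within groups. The array with the highest score was taken in each group, so 1 array per group was set by this rule and is not a result. These were Mock Tet+ 2 (score 12.25), Mock Tet- 1 (8.06), RPF1 Tet+ 3 (17.76) and RPF1 Tet- 2 (21.57). In the RPF1 arrays of this set, several genes induced by ERK signalling were low. Others were not low in both, such as FOSB, with deviations of 0.13 in RPF1 Tet+ 3 and -0.39 in RPF1 Tet- 2, and MYC, with 0.03 and -0.17. ETV5 deviated from its group mean by -1.85 in RPF1 Tet+ 3 and -1.31 in RPF1 Tet- 2, ETV4 by -1.15 and -1.18, FOSL1 by -0.93 and -0.75, and DUSP4, a phosphatase of ERK, by -0.75 and -0.89. TXNIP, a gene raised by glucose, deviated by 0.86 and 0.71. In the Mock arrays of the set, Mock Tet+ 2 and Mock Tet- 1, ETV5 deviated by -0.41 and -0.14 and FOSL1 by -0.38 and -0.05. ETV4 (0.07 and -0.04) and DUSP4 (0.015 and 0.22) were not low there, and TXNIP was at 0.255 and -0.04. The Mock arrays thus largely lacked the pattern of the RPF1 arrays in these genes. EGR1, an immediate early gene, had opposite signs, with 1.35 and 0.96 in these Mock arrays and -0.88 and -0.52 in the RPF1 arrays.

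By list, genes at the low end of this component were those of FGF and ERK signalling (camera adjusted p = 2.66e-10 on the loadings), MYC and ribosome biogenesis (1.75e-07), NF-kB and inflammation (1.75e-07), the mitochondrial ribosome (0.00568), oxidative stress and NRF2 (0.0177) and histones (0.041). Cholesterol synthesis genes (0.000192) and extracellular matrix genes (0.00463) lay at the high end. The p-values are across genes, which are not independent replicates, and the arrays were chosen from these data, so they describe these arrays only. No explanation was tested.

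The third pattern weighed is the set of genes called between RPF1 Tet+ and Mock Tet+ in medium with Tet. Chips are argued against: for 720 genes picked on other arrays, the median change between held-out arrays on the second chip was 0.829 of that in the picking arrays, and 94.3% kept their sign. Partial induction in RPF1 Tet+ cells may still play a part for some genes, but genes picked as induced moved in RPF1 Tet+ against Mock Tet+ by ratios of -0.118, -0.0586 and at most 0.0161 of the induced change in 3 rotations. These are under the 0.1 that partial induction of the whole set would need, though the last is above the 0 set to exclude it. A difference between the transfected lines unrelated to RPF-1 cannot be told apart from an effect of the construct with 1 line of each kind.

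For the other comparisons the 10 splits of 6 arrays are too few for a share under 0.05. RPF1 Tet+ against Mock Tet+ had 2000 real calls and RPF1 Tet- against Mock Tet- 4135, with 0 as the highest of the others in each. Mock Tet- against Mock Tet+ had 0 by limma, with 327 genes at an unadjusted p under 0.05 and 1 call as the highest of the others.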
